A study of Arabidopsis thaliana with 13 samples.

How the data were processed

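Small RNA libraries of immature inflorescences of Arabidopsis thaliana were sequenced on an Illumina GAIIx per the labels, and 13 libraries were used: 3 of Col-0 wild type, 3 of nrpe1, and 1 each of the T+S wild type, dms4, drd1, dms3, rdm1, nrpd1 and rdr2. The deposited files hold raw counts per the labels: adapters had been removed by the authors, identical reads had been collapsed, and each distinct sequence was listed with the count of its reads. The values were checked and were whole numbers of at least 1. The build named in the submitters' processing notes is TAIR9, but the files hold no coordinates, and every position given here comes from a new match to the TAIR10.1 assembly. The adapter trimmer and the aligner are not given in the sources used here.

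Sequences of 18 to 30 nt were placed on the nuclear and organelle genomes by perfect match with a program written in Python 3.11.15 with numba 0.67.0, numpy 2.4.6 and pandas 2.3.3. The library size was the number of reads with a nuclear match, outside organelles, annotated rRNA, tRNA, snRNA and snoRNA genes and the 45S rDNA repeat. The 45S repeat was left out after the data were seen, because its 25S gene is not annotated as rRNA, and a library size with 25S matches was run as an alternative. The library size ranged from 1273956 to 16405087 reads, and 1 read corresponded to 0.061 to 0.785 RPM. Bins and genes were counted with reads that match the genome once. Bins were 500 bp wide, genes comprised the body and 1 kb upstream of the start, and features with at least 10 reads in at least 3 of the 6 Col-0 and nrpe1 libraries were tested. miRNAs and trans-acting siRNAs were counted by exact sequence from a list of 46. Intervals are exact 95% intervals (Clopper-Pearson for shares, from scipy 1.17.1), and folds against 0 reads use a floor of 3 reads over the group.

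Replicates of each group were compared pair by pair with a chi-square over features with at least 20 reads in the pair. The nrpe1 libraries 2 and 3, labelled as biological replicates, agree within sampling noise in bins (chi-square per degree of freedom 0.982, p = 0.927). In genes the chi-square per degree of freedom was 1.04 (p = 0.0252), and in miRNAs it was 13.7 (p = 7.91e-91), so there the pair differed by more than sampling noise, although by less than every other pair. Their counts were summed to 1 sample in the main tests. This choice departs from the planned 3 against 3 libraries and was made after the data were seen, and all 6 libraries as separate samples were run as an alternative. The replicate numbers were not used to pair the groups in the bins and genes tests. Residuals of libraries 1 of both groups correlated at 0.161 in bins, but those of numbers 2 and 3 correlated across numbers (0.080 and 0.106) as they did within a number (0.081 and 0.097). In miRNAs the libraries of the same number correlated at 0.785, 0.668 and 0.691, each above 0.1, and those of numbers 2 and 3 across numbers at 0.690 and 0.694. The fit with the replicate block is therefore given beside the miRNA results where it changed a call.

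Changes between nrpe1 and Col-0 were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) on the library size without a scaling factor, with Benjamini-Hochberg adjustment and a threshold of 0.05. Shares of read sizes were compared with an exact two-sided permutation test of 3 against 2 samples. Annotation classes, taken at the midpoint of each bin, were compared with Fisher's exact test and with 10000 random sets matched on mean abundance. Gene-poor windows were 100-kb windows with fewer protein-coding genes than a fixed minimum. The single-library mutants were described by log2 ratios with a pseudocount of 0.5 RPM, with no test. The dms4, drd1, dms3 and rdm1 libraries were set against the T+S wild type, and nrpd1 and rdr2 against the mean of the Col-0 libraries.

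Lists, the rule for named genes, the planned tests and most alternatives were fixed before the data were examined. The sum of nrpe1 libraries 2 and 3, the library size without the 45S repeat and the annotation test of bins that rose came after. There were 12 lists, tested with camera of limma 3.58.1 with a preset correlation of 0.01 and with an estimated one: on 24-nt reads TAS loci, genes known as targets of DNA methylation, transposable element genes, pentatricopeptide repeat genes of chromosome 1, the RNA-directed DNA methylation machinery and photosynthesis genes; on 21-nt reads TAS loci and pentatricopeptide repeat genes; and 4 lists of miRNAs (phase change, trans-acting siRNAs with their triggers, nutrient and copper miRNAs, and miRNAs of small RNA pathway genes). The lists held 8, 17, 11, 14, 20 and 10 genes, and 3, 5, 8 and 3 small RNAs. Named genes were those with a symbol, past the gene test, with all 3 nrpe1 libraries beyond all 3 Col-0 libraries and at least 20 reads per library on average: the 10 with the largest fall and the 10 with the largest rise. The 5 bins with the largest fall and the 5 with the largest rise were taken by the same rule, members of the lists could be named, and the mutated genes were given in every library. The rule also allowed 5 miRNAs in each direction past adjusted p 0.05, of which there were 0 by edgeR. Under this rule 780 genes with a symbol were lower and 21 higher.

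The tests were checked on simulated data with the measured spread. The simulations changed 200 of 16197 bins, 200 of 8040 genes and 12 of 42 miRNAs, as many up as down. The data called far more bins and genes, mostly lower, so the rates hold for the simulated setting only. In bins, 85% of 4-fold and 23% of 2-fold changes were recovered with 4.4% false calls. In genes these values were 95%, 32% and 2.3%. For miRNAs, 0% of 4-fold and 0% of 2-fold changes were recovered, with 0 calls. The biological coefficient of variation behind these values was 0.214, 0.202 and 0.596. The annotation test gave 1 of 20 simulated sets under 0.05 at an odds ratio of 1 and 20 of 20 at an odds ratio of 2. Matches of translated reads to peptides of transgene marker proteins were sought in all 6 reading frames, with the reversed proteins as a control. Alternatives comprised TMM factors, DESeq2 1.42.0, scaling on the listed miRNAs, other library sizes, other filters, bin widths, read sizes and pseudocounts, reads shared over all matches, replicate blocks, and each library left out in turn. Figures were drawn with matplotlib 3.10.9. Reads without a perfect match and reads outside 18 to 30 nt were left out. Transposable elements were not counted as a class because the annotation has no class for them.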

Results

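Small RNAs of immature inflorescences of Arabidopsis thaliana were profiled by sequencing in 13 libraries, all in the Col-0 background. Col-0 wild type and the nrpe1 mutant (nrpd1b-1, mutated in the largest subunit of RNA polymerase V) had 3 libraries each, labelled as biological replicates. A further 7 libraries were single: a wild-type plant named T+S in the labels (here the T+S wild type), the 4 mutants for which it is the control (dms4, drd1, dms3 and rdm1), nrpd1 (nrpd1a-4, RNA polymerase IV) and rdr2-1 (an RNA-dependent RNA polymerase). The files gave each distinct sequence with its raw read count. Reads of 18 to 30 nt were placed on the TAIR10.1 genome by perfect match, and 53.5% to 88.9% of them matched. Levels are RPM, reads per 1000000 reads of the library size, which is the number of nuclear genome-matched reads outside structural RNA genes and the 45S rDNA repeat. The library size was 1637208, 6117493 and 4907012 reads in Col-0 replicates 1 to 3 and 1273956, 4514055 and 4252343 reads in nrpe1 replicates 1 to 3. It was 5111169 reads in the T+S wild type, 3958233 in dms4, 13079655 in drd1, 16405087 in dms3, 13429905 in rdm1, 2869641 in nrpd1 and 4353844 in rdr2. A floor of 3 reads corresponded to 0.183 RPM in the deepest library, dms3, and to 2.36 RPM in the shallowest, nrpe1 replicate 1. Intervals and floors cover counting error only, because sequenced reads are not independent molecules after PCR.

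The mutated genes were looked at first in every library. Small RNA reads do not measure the transcript, so they do not check whether a gene was knocked out. NRPE1 (AT2G40030, chromosome 2, 16714460 to 16723718, annotated with the symbol NRPD1B) carried 29.0, 20.8 and 23.8 RPM of 20- to 25-nt reads in nrpe1 replicates 1 to 3. The same gene carried 1.22, 0.49 and 0.41 RPM in the Col-0 replicates and at most 3.48 RPM in any other library. These nrpe1 reads (37, 94 and 101 reads) lay mainly in the 500-bp bins that start at positions 16720501 to 16722001. NRPD1 (AT1G63020) carried 1.39 RPM, or 4 reads, in nrpd1 and at most 3.14 RPM elsewhere. RDR2 (AT4G11130) carried 2.53 RPM in rdr2 and 0.16 to 2.02 RPM elsewhere. DRD1 (AT2G16390) carried 0.92 RPM in drd1, DMS3 (AT3G49250) 0.06 RPM in dms3, RDM1 (AT3G22680) 0.15 RPM in rdm1, and DMS4 (AT2G30280) 0 reads in dms4, where a count of 0 allows up to 0.758 RPM.

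**Figure D1:**
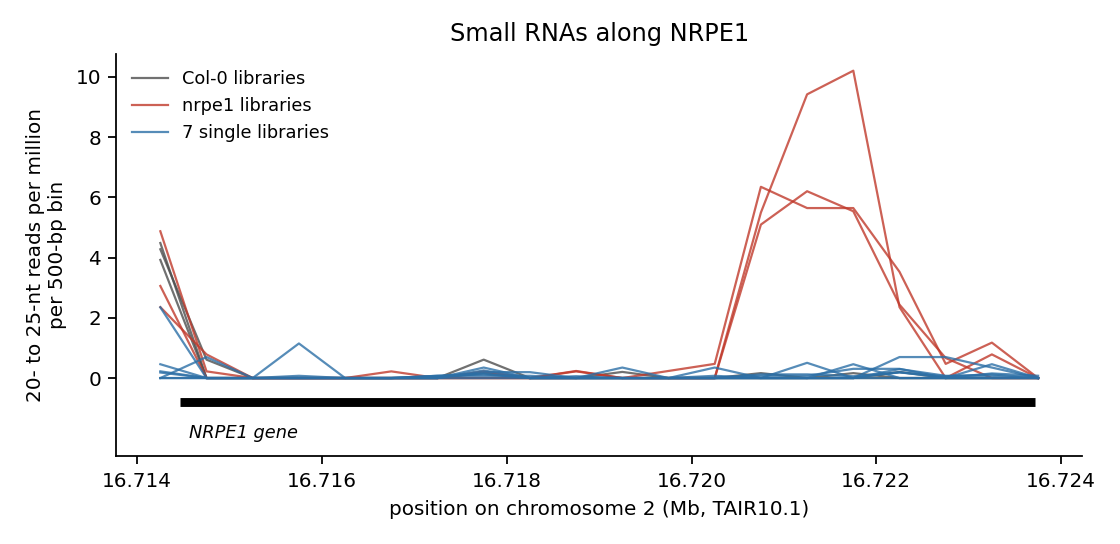
Reads of 20 to 25 nt in RPM (vertical axis) in 500-bp bins along NRPE1 on chromosome 2 (horizontal axis, position in Mb; the black bar is the gene), with 1 line per library. The 3 nrpe1 libraries lie above the others in the bins that start at 16720501 to 16722001.

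The replicates were compared before testing. The nrpe1 libraries 2 and 3 agree within sampling noise in the bins described next, with a chi-square per degree of freedom of 0.982 over 12569 bins. The other pairs of replicates of a group gave 2.47 to 5.57 in bins. Over genes the value of this nrpe1 pair was 1.04, against 2.59 to 5.56 in the other pairs, and over 41 miRNAs it was 13.7, against 173 to 1054. These 2 libraries were therefore counted as 1 sample, which left 3 Col-0 samples and 2 nrpe1 samples. The p-values of the main tests of bins, genes, miRNAs and size shares measure the spread between these samples. Those of the annotation classes are taken over bins and hold no spread between samples. Alternatives with a replicate block, with all 6 libraries as separate samples or without both libraries numbered 1 keep nrpe1 libraries 2 and 3 apart.

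The first comparison asked how the sizes of small RNAs differ when RNA polymerase V is mutated. Reads of 24 nt, the size of the siRNAs of RNA-directed DNA methylation, made up 56.7% ± 0.793 (SD, n = 3) of the library size in Col-0 and 39.1% ± 10.2 (SD, n = 2) in nrpe1. The 3 nrpe1 libraries held 31.95%, 47.4% and 45.3%, all below the 3 Col-0 libraries, which held 57.6%, 56.3% and 56.1%. Reads of 21 nt, the size of most miRNAs and trans-acting siRNAs, made up 17.99% ± 1.42 in Col-0 and 30.1% ± 4.57 in nrpe1. The 22-nt share was 8.33% ± 0.390 in Col-0 and 11.7% ± 0.653 in nrpe1, and the 23-nt share was 10.8% ± 0.371 and 7.44% ± 0.675. An exact two-sided permutation test gave p = 0.1 for each of the 4 sizes, adjusted p = 0.1, which is the smallest p this design allows, so no size passed. The difference in the 24-nt share was -17.5 points with all libraries and -10.3 points without nrpe1 replicate 1, the shallowest library. That library also held the largest 45S share of the group, 30.2% against 10.8% and 11.3% in the other nrpe1 libraries. Structural RNA matches were 21.8%, 13.1% and 13.4% in nrpe1 replicates 1 to 3 and 12.7%, 9.3% and 9.5% in the Col-0 replicates. Organelle matches were 6.8%, 4.4% and 4.4% in nrpe1 and 4.1%, 3.5% and 3.2% in Col-0. Both shares were thus higher in every nrpe1 library, and the cause was not tested.

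**Figure D2:**
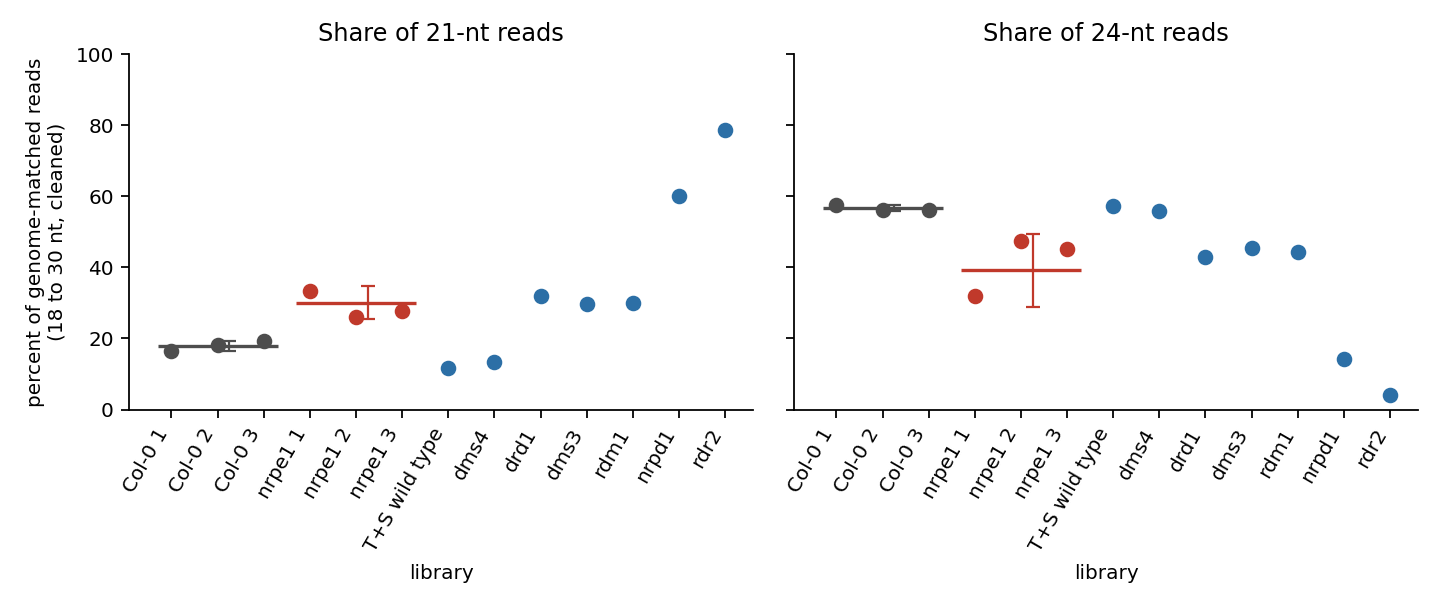
Percent of the library size (vertical axis) made up by reads of 21 nt and of 24 nt (1 panel each) in each library (horizontal axis), with 1 point per library and the mean and SD of Col-0 (n = 3) and nrpe1 (n = 2) as a line and an error bar. The 24-nt share of nrpe1 (31.95% to 47.4%) lies below that of Col-0 (56.1% to 57.6%), and rdr2 has the lowest 24-nt share, 3.98%.

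The next comparison asked which regions of the genome depend on RNA polymerase V for their 24-nt siRNAs, the question named in the design of the series. The 5 chromosomes were divided into 500-bp bins, and 24-nt reads with 1 match in the genome were counted. Loss of 24-nt siRNAs was widespread in nrpe1 and was most frequent just upstream of protein-coding genes. Of 2626 tested bins within 1 kb upstream of a protein-coding gene, 65.2% fell and 3.1% rose. Of 1800 bins in protein-coding gene bodies 36.2% fell, of 362 bins in other noncoding genes 36.5%, and of 7329 intergenic bins 34.2%. Bins in annotated pseudogenes, 4080 in number, behaved differently: 5.6% fell and, with the library size, 12% rose. In gene-poor windows of 100 kb, 14.1% of bins fell, against 46.4% in the other windows. Each of the 5 chromosomes had 29.6% to 35.2% of its tested bins fall.

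Over the genome, 5235 of 16197 tested bins fell and 1425 rose by edgeR's quasi-likelihood test at an adjusted p of 0.05. The bins that fell had a median log2 fold change of -3.34 (quartiles -5.06 and -1.75), and 2872 of them, 54.9%, were at least 8-fold lower. Among them, 162 had 0 reads in nrpe1, and with these set at their bound the median was again -3.34. The bins that rose had a median of 1.24 (quartiles 1.05 and 1.56). Bins that fell held 32.4% to 35.7% of the 24-nt reads of all tested bins in the Col-0 libraries and 7.99% to 8.56% in the nrpe1 libraries. They were also often isolated, since 49.2% had no tested bin beside them, against 28.2% of all tested bins and 13.1% of those that rose. In 37.0% of tested bins all 3 nrpe1 libraries lay below all 3 Col-0 libraries and in 12.7% above, where chance gives 10% for both directions together (20% for 3 samples against 2).

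The number of bins that rose depended on the scaling. The median log2 fold change of all bins was -0.23 with the library size and shifted by 0.33 with TMM factors, which called 4809 bins lower and 3381 higher (41.3% of calls higher, against 21.4%). It shifted by -0.63 when the libraries were scaled on listed miRNAs (6314 lower, 248 higher, 3.8% higher), by -0.26 with all genome-matched reads (5031 and 384, 7.1%) and by -0.14 with 25S matches in the library size (5060 and 606, 10.7%). It shifted by 0.18 with DESeq2, which also changes the test and called 4193 bins lower and 813 higher. Without Col-0 replicate 2 the bins that rose numbered 643, and without Col-0 replicate 3 they numbered 727.

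The annotation of the bins that fell was tested against the other tested bins. Upstream positions made up 32.7% of the bins that fell and 8.3% of the others, an odds ratio of 5.34. Pseudogenes made up 4.4% against 35.1% (odds ratio 0.08), and gene-poor windows 18.9% against 55.2% (odds ratio 0.19). Gene bodies differed little, with 12.5% against 10.5% (odds ratio 1.22), as did intergenic positions, with 47.9% against 44.0% (odds ratio 1.17). Against 10000 random sets of bins matched on mean abundance, adjusted p was 0.0004 for upstream positions, pseudogenes and gene-poor windows. It was 0.0021 for gene bodies, 0.0122 for intergenic positions and 0.771 for other noncoding genes (2.5% against 2.1%). Of the bins that rose, 59.2% lay in gene-poor windows against 41.9% of the others (odds ratio 2.01) and 5.8% upstream against 17.2% (odds ratio 0.29), each at an adjusted p of 0.0004. Pseudogenes held 34.3% of them against 24.3% (odds ratio 1.63, adjusted p of 0.0004), but this call depended on the scaling: the odds ratio was 2.55 with TMM factors (adjusted p of 0.0003), and the call against matched sets ended with 25S matches (0.99, adjusted p of 0.078), with all genome-matched reads (0.58, adjusted p of 0.17) and when scaled on listed miRNAs (0.45, adjusted p of 0.0801). With DESeq2 the odds ratio was 0.86, against 2.11 for edgeR with size factors of DESeq2, although the share of 22.6% was above that of matched sets, 17.4%. Neighbouring bins are not independent. The annotation used has no class for transposable elements, so these could not be counted as a class. Some transposable element genes, such as those of the list tested below, are in the annotation under its other classes. A class such as pseudogenes may therefore hold transposable element genes, and how many was not counted.

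**Figure D3:**
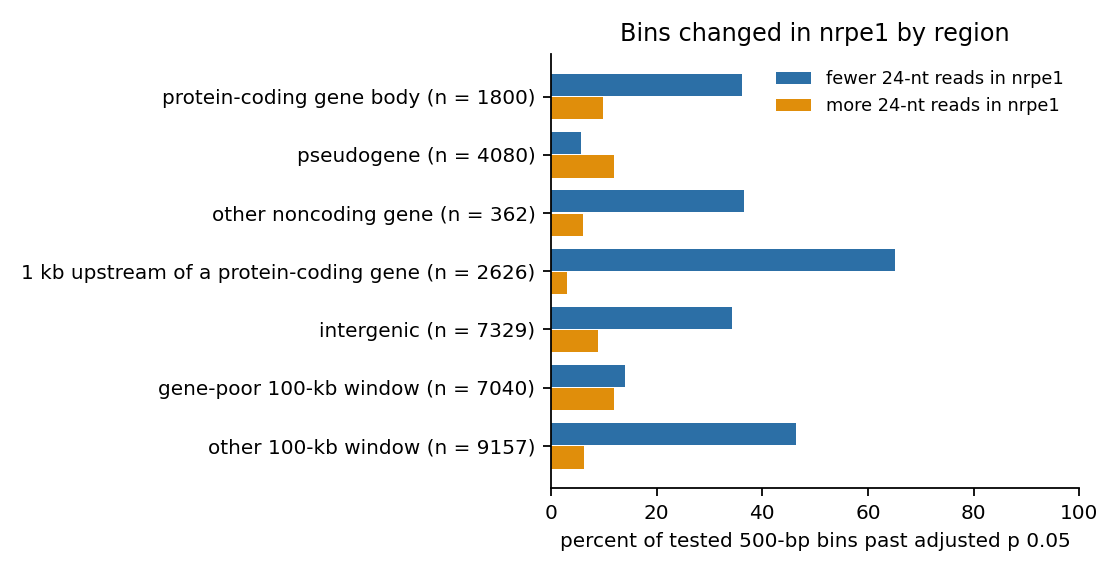
Percent of tested 500-bp bins (horizontal axis, n beside each name) that fell or rose in nrpe1 past an adjusted p of 0.05, for each annotation class and for gene-poor and other 100-kb windows (vertical axis). The share that fell is 65.2% upstream of protein-coding genes and 5.6% in pseudogenes.

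The 5 bins with the largest fall had 0 reads in all 3 nrpe1 libraries, so their folds are lower bounds against a floor of 3 reads over the group. They were the intergenic bin at chromosome 1, 18297501 to 18298000, 1430 bp from LCR16 (61.9 ± 19.5 RPM in Col-0, at least 228-fold lower), and the bin at 7281501 to 7282000 upstream of AT1G20910 (28.8 ± 2.21 RPM, at least 98.9-fold lower). The others were 10444001 to 10444500 in AT1G29830 (23.5 ± 3.30 RPM, at least 81.7-fold lower), chromosome 2, 6873001 to 6873500 at AT2G15780 (22.9 ± 4.54 RPM, at least 82.2-fold lower) and chromosome 1, 26953001 to 26953500 in AGL12 (22.8 ± 1.78 RPM, at least 78.5-fold lower). The largest rise was at chromosome 3, 15777001 to 15777500, at AT3G43970, from 1 read in Col-0 to 276 in nrpe1, a ratio of 348-fold with an exact counting interval of 62.0 to 13800. In AT5G44770 the bin at chromosome 5, 18065501 to 18066000, rose from 2 to 379 reads, a ratio of 239-fold (65.7 to 1980), and its neighbour at 18065001 rose by a log2 fold change of 5.49 (0.52 ± 0.63 to 14.9 ± 2.25 RPM). The remaining rises were 5.37 at chromosome 2, 5736501, in AT2G13770 and 4.88 at chromosome 4, 5734501, 2306 bp from AT4G08940. All SDs of Col-0 are over n = 3 and those of nrpe1 over n = 2.

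Genes were then tested with their body and the 1 kb upstream of their start, to ask at which genes the loss occurred. The 10 named genes with the largest fall lost nearly all 24-nt reads. AGL12 (AT1G71692, chromosome 1, 26952545 to 26955127), a MADS-box transcription factor of root and flowering development, went from 23.2 ± 2.10 RPM in Col-0 to 0 in nrpe1, at least 80.1-fold lower. GRX480 (AT1G28480), a glutaredoxin that binds TGA transcription factors, went from 17.6 ± 7.30 RPM to 0, at least 65.8-fold lower, and emb1379 (AT5G21140), named for an embryo-defective mutant, from 17.1 ± 2.50 RPM to 0, at least 58.4-fold lower. Also at 0 in nrpe1 were the transcription factors DOF4.5 (AT4G21080, 16.6 ± 0.66 RPM, at least 55.5-fold lower) and ATAF2 (AT5G08790, 10.06 ± 3.39 RPM, at least 35.7-fold lower) and the miRNA gene MIR5635a (AT5G03145, 10.4 ± 0.82 RPM, at least 34.1-fold lower). ARFC1 (AT3G22950), a GTPase of the ADP-ribosylation factor family, fell from 68.1 ± 14.3 RPM to 2 reads, a ratio of 366-fold (exact counting interval 101 to 3020). CPL2 (AT5G01270), a phosphatase of the RNA polymerase II tail, fell to 1 read, a ratio of 259-fold (46.1 to 10200). HVT1 (AT2G30800), a helicase of vascular tissue and tapetum, and MEE32 (AT3G06350), an enzyme of the shikimate pathway, also fell to 1 read, with ratios of 229-fold (40.8 to 9080) and 209-fold (37.1 to 8270).

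For emb1379, DOF4.5, ARFC1, CPL2, HVT1 and MEE32, 98.1% to 100% of the reads lay upstream of the gene, whereas AGL12 had 2.0% and GRX480 0.0% there. Genes that gained 24-nt siRNAs changed less. ASY2 (AT4G32200), a paralogue of the meiotic axis protein ASY1, rose from 1.21 ± 0.59 to 15.55 ± 12 RPM, a log2 fold change of 3.70. MRD1 (AT1G53480) and HEI10 (AT1G53490), a factor of meiotic crossover formation, overlap and share the same reads, and rose by 3.45, from 0.97 ± 0.45 to 11.2 ± 3.55 RPM. BIP1 (AT5G28540), a chaperone of the endoplasmic reticulum, rose by 2.52, from 11.9 ± 1.28 to 69.0 ± 5.40 RPM, with 98.6% of its reads upstream. The others were MIR8168 (2.09), the F-box gene FBS3 (1.88), MIR4245 (1.54), the fucosyltransferase gene FUT9 (1.43), the histone H2A gene HTA4 (1.35) and the auxin response factor gene ARF23 (1.31).

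In total, 3215 of 8040 tested genes fell and 591 rose by edgeR's quasi-likelihood test. All 3 nrpe1 libraries lay below all 3 Col-0 libraries in 44.1% of genes and above them in 12.1%, beside the same chance shares of 10% and 20%. The count of genes that rose moved with the scaling: 2415 with TMM factors (46.3% of calls higher, against 15.5%), 124 with all genome-matched reads (3.8%), 75 when scaled on listed miRNAs (1.9%) and 211 with 25S matches in the library size. Without Col-0 replicate 2, Col-0 replicate 3 or nrpe1 replicate 1 it was 248, 275 or 1000. The median log2 fold change of all genes was -0.36 and shifted by 0.51 with TMM factors, by 0.31 with DESeq2, by -0.64 when scaled on listed miRNAs, by -0.27 with all genome-matched reads and by -0.15 with 25S matches. Of the named rises, MIR4245 (0.85), FUT9 (0.77), HTA4 (0.64) and ARF23 (0.65) missed the threshold when scaled on listed miRNAs, and HTA4 (1.05) and ARF23 (1.03) also with all genome-matched reads.

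**Figure D4:**
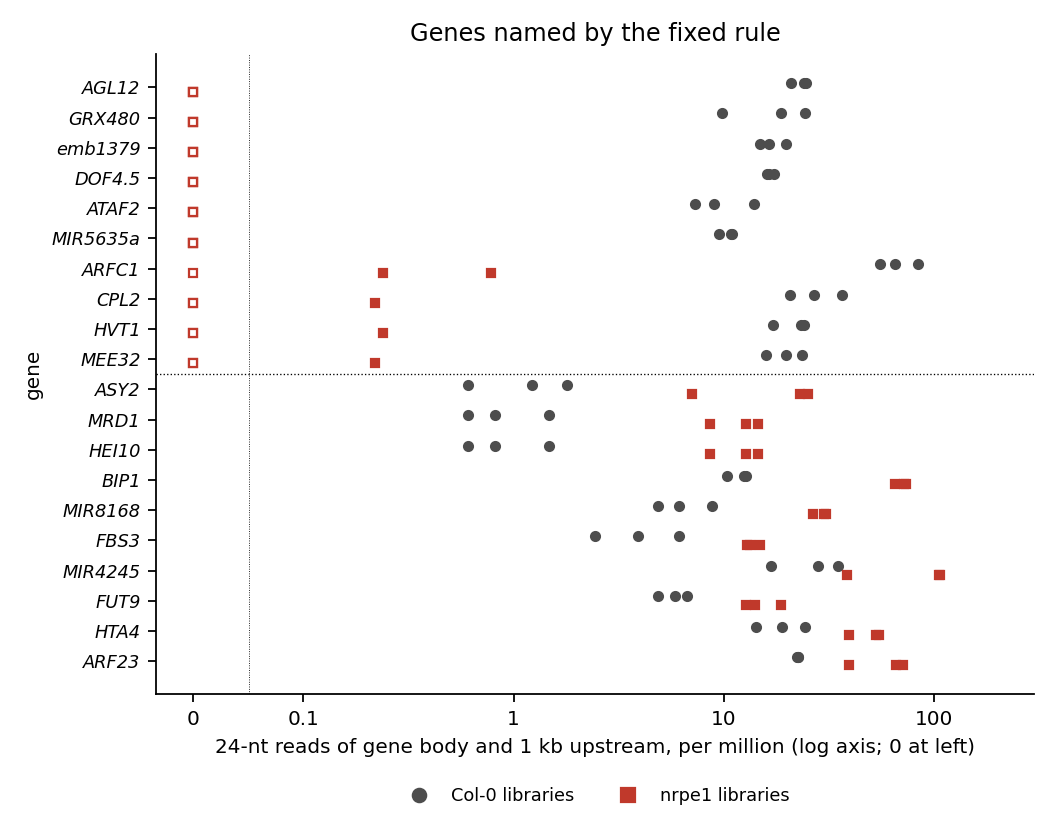
Level of 24-nt reads in RPM (body and 1 kb upstream) of the named genes (horizontal axis, log scale with 0 drawn apart at the left) for each of the 20 named genes (vertical axis), with 1 point per Col-0 or nrpe1 library. AGL12 lies between 20.8 and 24.7 RPM in Col-0 and at 0 in nrpe1, and BIP1 lies between 10.4 and 12.8 RPM in Col-0 and between 65.2 and 73.4 RPM in nrpe1.

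Gene groups were examined through lists. Among genes of the RNA-directed DNA methylation machinery, 4 of 6 tested members lost 24-nt siRNAs. SUVH9, a protein that binds methylated DNA and recruits RNA polymerase V, fell from a range of 39.9 to 45.9 RPM to 3 reads, a ratio of 144-fold (exact counting interval 49.0 to 701). NRPD2A, the subunit shared by RNA polymerases IV and V, fell by 4.64 on the log2 scale, DMS11 (MORC6) by 3.06 on the log2 scale and DCL3, the dicer of 24-nt siRNAs, by 3.05 on the log2 scale. DRD1 (-0.27) and NRPE1 itself (0.70) did not pass. Of genes known as targets of DNA methylation, 3 of 8 fell, namely FWA (-2.98), PUM9 (-2.04) and ALN (-0.84), while SDC (0.43), QQS (0.03), IBM1 (-0.06), SNC1 (-0.38) and HDG9 (-0.72) did not pass. The other listed genes, among them ROS1, had too few reads to be tested. ALN missed the threshold with TMM factors (-0.34), without Col-0 replicate 2 (-0.78) and without Col-0 replicate 3 (-0.85).

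Of 6 tested transposable element genes of the list, AT1G58140 (-5.65) and AT1G21945 (-2.70) fell and AT1G48710 rose (0.80). The last of these missed the threshold when scaled on listed miRNAs (0.18), with 25S matches (0.65) and without Col-0 replicate 1 (0.73), 2 (0.96) or 3 (0.76) or nrpe1 replicate 2 (0.69). Of 3 tested pentatricopeptide repeat genes of chromosome 1, RPF3 (-3.32) and AT1G63630 (-5.42) fell. Of the loci of trans-acting siRNAs (TAS), whose main products are 21 nt long, 3 of 7 lost 24-nt reads: TASIR-ARF (-4.26), TAS3 (-1.75) and TAS1A (-0.82). TAS1A missed the threshold with TMM factors (-0.27), with 25S matches (-0.98) and without Col-0 replicate 1 (-0.84), 2 (-0.79) or 3 (-0.85), nrpe1 replicate 1 (-0.50) or nrpe1 replicate 3 (-0.71). Of 2 tested photosynthesis genes, which served as markers of green tissue, LHCA3 fell (-2.10) and RBCS1A did not pass (-0.10). With TMM factors NRPE1 (1.18), SDC (0.98), TAS1C (0.73) and AT4G08680 (0.72) also passed as higher, and when scaled on listed miRNAs TAS1B (-1.28), HDG9 (-1.40), AT2G04770 (-1.34) and AT5G13205 (-1.26) passed as lower. SDC also passed with the replicate block (0.54), without nrpe1 replicate 1 (0.71) and without both libraries numbered 1 (0.68). HDG9 passed with that block (-0.60) and without both libraries numbered 1 (-0.28), as did TAS1C (0.39) and AT2G04770 (-0.97) without these. Counts adjusted over the list alone were the same as over all genes for these 6 lists. No list differed from the other genes by limma's camera: the lowest adjusted p was 0.586 with the preset correlation, and the lowest adjusted p = 0.888 with an estimated correlation.

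On 21-nt reads, 5 of 7 TAS loci were higher in nrpe1 over all genes tested and 6 of 7 adjusted over the list alone. TAS2 had a log2 fold change of 1.23, from 2548 to 3642 RPM in Col-0 to 5222 to 9317 RPM in nrpe1. The others past the test over all genes were TAS1A (1.11), TAS1C (1.05), TAS3b (1.04) and TASIR-ARF (1.03), and TAS1B (0.96) was added over the list alone. Of 11 tested pentatricopeptide repeat genes, 7 were higher by both counts, among them AT1G62914 (1.26), AT1G63150 (1.24) and AT1G63080 (1.24). The 21-nt reads of all 1947 tested genes had a median log2 fold change of 0.87, with 751 higher and 76 lower, so the medians of both lists (1.04 and 0.97) lay near that of all genes. With TMM factors 57 were higher and 137 lower, and when scaled on listed miRNAs 80 were higher and 100 lower. Without Col-0 replicate 2, Col-0 replicate 3 or nrpe1 replicate 1, 353, 331 or 494 were higher. With TMM factors, which shifted this median by -0.85, and with scaling on listed miRNAs, which shifted it by -0.63, none of the genes of these lists passed (TAS2 0.29 and 0.44). Without Col-0 replicate 2, Col-0 replicate 3 or nrpe1 replicate 1 none of the 7 TAS loci passed (TAS2 1.24, 1.10 and 0.76), and 2, 1 and 4 of the pentatricopeptide repeat genes did. With the replicate block 7 of 7 TAS loci and 9 of 11 pentatricopeptide repeat genes were higher over all genes, and 7 and 8 were without both libraries numbered 1. By camera these lists gave adjusted p = 0.888 with an estimated correlation.

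The miRNA comparison asked whether mature miRNAs and trans-acting siRNAs differed between nrpe1 and Col-0. Of 42 tested sequences, edgeR's quasi-likelihood test called 0, with 6 at an unadjusted p under 0.05, and DESeq2 called 2, miR319a and miR166a, as lower. The 6 were all higher in nrpe1: miR167a (1.34), miR396a (1.46), miR396b (1.41), miR403, miR2111a (2.90) and TAS1_siR255 (2.35), beside a median of all 42 of 0.85. That median was -0.09 with TMM factors. The spread between samples was large: in simulated data of this spread 0% of 4-fold changes were recovered, against 85% in bins and 95% in genes. Libraries numbered 1 stood apart in both groups. In them miR408, which targets copper proteins, was at 755 and 1187 RPM against 22.01 to 30.3 RPM in the other libraries, and miR845a, known from pollen, at 3.67 and 4.71 RPM against 212 to 328 RPM. Without both libraries numbered 1, a choice made after the data were seen, 13 sequences were higher and 1, miR319a, was lower (-1.67). In that fit nrpe1 libraries 2 and 3 entered as separate samples. Without Col-0 replicate 1 alone 7 were higher. The miRNA lists (phase change with 3 tested members, trans-acting siRNAs and their triggers with 5, nutrient and copper miRNAs with 5, and miRNAs of small RNA pathway genes with 3) had 0 members called, also adjusted over the list alone, where 6 sequences of all 42 passed an unadjusted p of 0.05 and DESeq2 called 2. With the replicate block 0 members were called over all 42, but adjusted over the list alone 3 of 3 phase-change miRNAs, 2 of 5 trans-acting siRNAs and triggers and 2 of 3 miRNAs of small RNA pathway genes were called as higher. Without Col-0 replicate 1, TAS1_siR255 (2.77), miR408 (4.71), miR2111a (3.19) and miR403 (2.72) were called over all sequences, but this setting leaves nrpe1 replicate 1 without its counterpart: miR408 was at 1187 RPM there and at 24.8 and 30.3 RPM in nrpe1 replicates 2 and 3. Without nrpe1 replicate 1, 0 were called, and the mean log2 fold change of the nutrient and copper list went from 1.53 to -0.34. Without both libraries numbered 1, miR157a (0.61), miR172a (0.69), TAS1_siR255 (1.27) and miR403 (1.35) were.

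The single-library mutants were compared with their controls to ask how their small RNAs differ in size. These libraries have no replicates, so their values carry no p and describe these libraries only. The 24-nt share was 57.2% in the T+S wild type (95% exact Clopper-Pearson interval 57.12 to 57.21) and 56.0% in dms4 (55.95 to 56.05). It was 43.0% in drd1 (42.97 to 43.03), 45.3% in dms3 (45.30 to 45.35) and 44.4% in rdm1 (44.37 to 44.42), mutants of 3 proteins that act together with RNA polymerase V. The lowest shares were 14.3% in nrpd1 (14.21 to 14.29) and 3.98% in rdr2 (3.97 to 4.00), beside 56.1% to 57.6% in the Col-0 libraries. The 21-nt share was 60.1% in nrpd1 and 78.6% in rdr2. Much of it was a single 21-nt miRNA, miR172a, at 377080 RPM in nrpd1 and 512472 RPM in rdr2. In the Col-0 libraries miR172a stood at 536 to 878 RPM. It stood at 196164, 163505 and 177983 RPM in drd1, dms3 and rdm1. In the T+S wild type it was at 27696 RPM and in dms4 at 28605 RPM. A high level of this sequence lowers the share of every other sequence, 24-nt reads included. The drd1, dms3 and rdm1 libraries had a longest read of 31 nt and the T+S wild type and dms4 of 36 nt, so the sequencing run and the genotype cannot be told apart in these 3. The distinct sequences of drd1 held 47.2%, of dms3 46.7% and of rdm1 48.6% 24-nt sequences, against 49.6% in the T+S wild type.

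The bins that fell in nrpe1 were then followed in these libraries, to ask whether the same regions depend on the other factors. Their median log2 ratio to the T+S wild type was -2.41 in dms4, -2.32 in drd1, -2.12 in dms3 and -2.10 in rdm1, and 71.4% to 80.9% of them were at least 2-fold lower. Bins not called in nrpe1 had medians of 0.26 to 0.33 in these mutants. Of the named genes, AGL12 had 4.50 RPM in the T+S wild type and 0 to 0.22 RPM in the 4 mutants, and ARFC1 had 53.2 RPM and 1.12 to 1.52 RPM. Bins that rose in nrpe1 had medians of 0.78 to 0.96, above the highest of 10000 matched random sets (0.32). The sets were drawn from all tested bins, those that fell in nrpe1 included, which lowers them. Scaled on listed miRNAs the medians of bins that rose were 0.69 in dms4 but -0.87 in drd1, -0.68 in dms3 and -0.78 in rdm1. The dms4 value was above its random sets, and the others were above theirs and below 0. In drd1, dms3 and rdm1 most listed miRNA reads were miR172a, so this scaling rests largely on a single sequence there. On the library size BIP1 was likewise higher, with log2 ratios of 1.32 to 1.91, and so was MIR8168, with 2.18 to 3.00. FBS3, in contrast, had 5.48 RPM in the T+S wild type and 0 to 0.25 RPM in the 4 mutants, although it rose in nrpe1, and ASY2 had log2 ratios of -0.67 to 0.03.

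In nrpd1 and rdr2, set against the mean of Col-0, 24-nt reads were lower in most regions. Of the bins not called in nrpe1, 74.8% were at least 2-fold lower in nrpd1 and 98.5% in rdr2, and of those that rose in nrpe1, 58.9% were at least 2-fold lower in nrpd1. These ratios use a library size that includes miR172a, at 377080 RPM in nrpd1 and 512472 RPM in rdr2 against 536 to 878 RPM in Col-0. Such a level lowers the RPM of every bin, and how much of the fall it accounts for was not tested. The median log2 ratio was -3.83 in nrpd1 and -4.59 in rdr2 for bins that fell in nrpe1, -1.97 and -3.14 for bins not called, and -1.31 and -2.78 for bins that rose in nrpe1. Random sets matched on abundance in Col-0 had medians of -3.35 in nrpd1 and -4.60 in rdr2 for bins that fell. For bins that rose these were -1.81 and -2.81. The sets were drawn from all tested bins, the compared bins included. How much of the difference between the classes goes with abundance therefore cannot be read from them. The Col-0 libraries had also served to choose these bins, so nrpd1 was set against the T+S wild type as well, with 1000 random sets matched on that library. There the median of bins that fell was -3.13 and the lowest random median -2.24 (-4.01 and -2.77 with a pseudocount of 0.1, -2.08 and -1.57 with 2). The rdr2 value was set by the pseudocount (-6.60 with 0.1 and -2.92 with 2), so it cannot show whether these bins differ from others in rdr2. HEI10 and MRD1 stood at 15.7 RPM in nrpd1 and 0.69 to 1.15 RPM in rdr2. The T+S wild type itself had a median of -0.75 against Col-0 for bins that fell in nrpe1, beside a median of -0.70 for random sets matched on Col-0. In the other direction, the Col-0 libraries had medians of 0.65 to 0.75 against the T+S wild type for these bins. Random sets matched on the T+S wild type had medians of 0.04 to 0.15 there. Whether the wild types differ more at these bins than at others thus depends on the library used for matching. The ratio of miR159b to miR159a was 0.092 in nrpd1, 0.079 in rdr2 and 0.08 in the T+S wild type but 1.31 to 2.24 in the Col-0 and nrpe1 libraries, so the comparison of nrpd1 and rdr2 with Col-0 crosses sets of libraries.

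**Figure D5:**
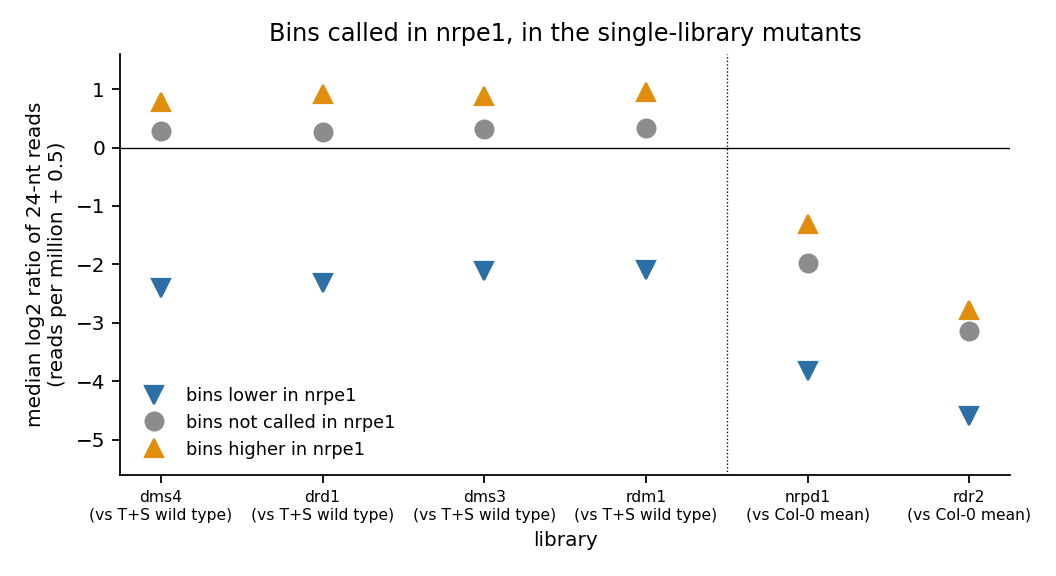
Median log2 ratio of 24-nt reads to the control library (vertical axis) in each single-library mutant (horizontal axis), for bins that fell, rose or were not called in nrpe1. Bins that fell in nrpe1 lie between -2.41 and -2.10 in dms4, drd1, dms3 and rdm1, and at -3.83 and -4.59 in nrpd1 and rdr2.

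The log2 ratios of the 4 mutants of the T+S line were compared with each other across the 16197 bins, which are not independent replicates. Pearson's r was 0.954 for drd1 and dms3, 0.948 for drd1 and rdm1 and 0.962 for dms3 and rdm1. It was 0.829, 0.843 and 0.840 for dms4 with drd1, dms3 and rdm1. Unchanged libraries simulated with the same shared control gave 0.526 to 0.610, and covariances of 0.158 where the measured ones were 2.68 to 3.21. Their spread was that measured between the Col-0 and nrpe1 samples (biological coefficient of variation 0.214). The T+S line has no replicates, so its own spread and differences between sequencing runs were not simulated. In dms4 and drd1 4015 bins were at least 2-fold lower in both. Independence gives 1622 but does not allow for the shared control, and the simulated unchanged libraries with that control gave 80.2. The simulated values hold for the simulated spread only and may be too low for these libraries. Within the bins not called in nrpe1, dms4 correlated with the other 3 at 0.388 to 0.405, below the simulated 0.528 to 0.535, while the covariances were 0.304 to 0.351 against a simulated 0.163, and 271 to 336 bins were at least 2-fold lower in both against a simulated 49.4 to 52.1. In the same bins drd1, dms3 and rdm1 correlated with each other at 0.870 to 0.872, against a simulated 0.609 to 0.617, with covariances of 0.667 to 0.777 against a simulated 0.163. The control was a single library, so it could not be divided between the mutants, and drd1, dms3 and rdm1 share their longest read length.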

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

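All tests in this part were chosen after the results were seen. Reads whose translation matches neomycin phosphotransferase II (NPTII), the kanamycin resistance marker of many T-DNA vectors, stood at 6248, 4679 and 4672 RPM in nrpe1 replicates 1 to 3 and at 1231 RPM in nrpd1, where the highest Col-0 library had 19.5 RPM. These and the values of the T+S line stood out because the lower end of their exact counting interval lay above the upper end in every control library, in reads that no comparison of the report used. In nrpe1, 61.6% to 68.7% of these reads were 21 nt and 9.0% to 12.2% were 24 nt long, and in nrpd1 25.2% were 21 nt and 49.8% were 22 nt long.

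Chance matches were argued against, since matches to the reversed protein came to at most 0.0284% of those to the protein in nrpe1. Carry-over into nrpe1 from another library was also argued against, because the highest level outside nrpe1 was 1231 RPM and the lowest nrpe1 level 4672 RPM. The same held for carry-over of reads from a finished nrpe1 library into nrpd1: miR159b in nrpd1 was at 0.192% of the lowest nrpe1 library, where the marker level would need 19.7%. The level of miR159b differed between sets of libraries, with 3.13 RPM in the T+S wild type. It therefore cannot speak to material mixed before library preparation. For nrpe1, an insertion with the marker in the mutated gene is a candidate explanation, since 20- to 25-nt reads of NRPE1 were 5.98 times as high in the lowest nrpe1 library as in the highest other library. For nrpd1 such an insertion stays open, with reads of NRPD1 at 0.44 times the highest other library and 4 reads behind them.

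In the T+S line, reads matching green fluorescent protein (GFP) stood at 4.80 RPM in dms4 and 25.2 RPM in rdm1, above 0.783 RPM in the T+S wild type. Reads matching hygromycin phosphotransferase (HPT) stood at 94.7 RPM in dms4 and 46.4 RPM in rdm1, above 21.3 RPM in the T+S wild type. NPTII reads stood at 15.8 RPM in rdm1, above 1.37 RPM in the T+S wild type. In drd1 and dms3 HPT reads stood at 4.36 and 4.02 RPM and GFP reads at 0.382 and 0.305 RPM, below the T+S wild type. NPTII reads there stood at 2.06 and 1.65 RPM, near those of the reversed protein, the control for chance matches, at 1.68 and 1.16 RPM. Matches to reversed GFP stood at 0.076 RPM in drd1 and 0.305 RPM in dms3, and to reversed HPT at 1.61 and 1.22 RPM. In rdm1 the reversed NPTII protein gave 1.04 RPM. No explanation was tested for any of these values in the T+S line.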

How the results depend on the processing

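Most alternatives were planned; all 6 libraries as separate samples, 25S matches in the library size and leaving out both libraries numbered 1 were chosen after the data were seen, as were miRNA scaling for lists and annotation, the annotation of bins that rose, the scalings of 21- and 22-nt bins and the random sets matched on the T+S wild type. Of 22 alternatives, 19 left the count of lower bins within 1.5 times of 5235 (4598 to 5246 without 1 library) and 20 that of lower genes within 1.5 times of 3215 (2885 to 3254). Of the lower bins 80.1% (DESeq2) to 100% were shared with each alternative that tested these bins, and of the lower genes 80.1% to 100%. Lower bins numbered 8903 of 104294 with no low-count filter, 2190 of 6095 with a filter of 30 reads and 8228 of 27125 with reads shared over matches, and lower genes 1759 of 4623 with a filter of 30 reads and 800 of 4138 for the gene body alone, where the number tested also differed. The 24-nt share of nrpe1 minus Col-0 was -18.05 to -10.3 points without 1 library, -9.88 without both libraries numbered 1 and -8.93 over distinct sequences. Paired by replicate number it was -15.1, with an exact sign-flip p = 0.25, and this design cannot reach p under 0.05. Each annotation class of the bins that fell had the same outcome under the 5 alternatives run for it, and no list passed by camera under any of 12, the replicate block included.

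The counts that rose moved most. Higher bins, 1425 as reported, numbered 3381 with TMM factors, 813 with DESeq2, 606 with 25S matches, 248 scaled on listed miRNAs, 384 with all genome-matched reads, 441 with a filter of 30 reads, 3118 with reads shared over matches, 2811 with reads of 20 to 25 nt and 3179 without both libraries numbered 1. With a replicate block over 6 separate libraries they numbered 2264, and 4094 with TMM factors added. They ranged from 643 to 1996 without 1 library. Of the 1425, 17.4% were shared when scaled on listed miRNAs, 26.9% with all genome-matched reads and 100% with TMM factors. Higher genes, 591 as reported, numbered 2415 with TMM factors, 211 with 25S matches, 75 scaled on listed miRNAs, 124 with all genome-matched reads, 354 with a filter of 30 reads, 1183 with reads of 20 to 25 nt, 380 for the body alone, 384 for 1 kb upstream alone, 344 also at least 2-fold, 927 with 6 separate libraries and 1604 without both libraries numbered 1. With a replicate block they numbered 1134, and 2831 with TMM factors added, and they ranged from 248 to 1000 without 1 library. For miRNAs, DESeq2 called 2 lower, and leaving out both libraries numbered 1 gave 1 lower and 13 higher. Without 1 library 0 to 7 were higher and 0 lower, and with a replicate block 0 were called in either direction. Scaling shifted the median of all bins and genes, and for the other moves the cause was not tested. Where nrpe1 replicate 1 was left out, the lone nrpe1 sample was assumed to vary like Col-0. Where both libraries numbered 1 were left out, nrpe1 libraries 2 and 3 entered as separate samples. These libraries agree within sampling noise in bins, so the spread behind those calls may be too small.

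The annotation of the bins that rose was run under 10 alternatives, all chosen after the data were seen. Gene-poor windows (odds ratios 1.29 to 8.13) and upstream positions (0.28 to 0.45) had the same outcome in each. The odds ratio of pseudogenes fell below 1 under 3 scalings: 0.45 scaled on listed miRNAs, 0.58 with all genome-matched reads and 0.99 with 25S matches, and none of these passed against matched sets (adjusted p of 0.0801, 0.17 and 0.078), so the call ended there. It was 0.86 with DESeq2 but 2.11 for edgeR with size factors of DESeq2, so there the test and not the scaling made the difference. With DESeq2 their share, 22.6%, was above that of matched sets (17.4%) although below that of the other bins (25.3%). Intergenic positions passed in both directions: 0.68 with reads shared over matches, 0.84 with 6 separate libraries, 0.86 without both libraries numbered 1, 0.78 with TMM factors and 0.85 for edgeR with size factors of DESeq2, but 1.14 also at least 2-fold, 1.42 with DESeq2, 2.07 scaled on listed miRNAs, 1.98 with all genome-matched reads and 1.47 with 25S matches. Gene bodies passed at 1.14 with reads shared over matches, and other noncoding genes at 0.52 also at least 2-fold, 0.65 with 6 separate libraries and 0.67 with TMM factors. The set of bins differs between these alternatives, and the cause of the other moves was not tested.

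In the single libraries the 24-nt share of the T+S wild type, dms4, drd1, dms3, rdm1, nrpd1 and rdr2 was 54.9%, 50.9%, 39.6%, 42.1%, 40.7%, 11.5% and 6.74% of all genome-matched reads, 49.6%, 48.3%, 47.2%, 46.7%, 48.6%, 32.2% and 16.1% of distinct sequences, and 56.2%, 53.8%, 41.5%, 44.1%, 42.9%, 12.7% and 5.96% with 25S matches. The median log2 ratios of bins that fell in nrpe1 were negative under every alternative. In dms4, drd1, dms3, rdm1, nrpd1 and rdr2 they were -3.14, -3.00, -2.70, -2.63, -4.81 and -6.60 with a pseudocount of 0.1, -1.56, -1.50, -1.36, -1.36, -2.53 and -2.92 with a pseudocount of 2, and -3.33, -3.33, -3.07, -3.04, -3.13 and -4.06 against the other wild type. Scaled on listed miRNAs they were -3.38 in drd1, -3.08 in dms3, -3.19 in rdm1, -4.55 in nrpd1 and -4.88 in rdr2. With reads shared over matches they were -2.48 in dms4, -2.41 in drd1 and -4.84 in rdr2, and with 25S matches -4.10 in nrpd1 and -4.51 in rdr2. In bins also at least 2-fold lower in nrpe1 they were -2.51, -2.43, -2.21 and -2.20 in dms4, drd1, dms3 and rdm1. In bins not called in nrpe1, Pearson's r of dms4 with drd1, dms3 and rdm1 was 0.388, 0.393 and 0.405, and r was 0.872 for drd1 and dms3, 0.870 for drd1 and rdm1 and 0.871 for dms3 and rdm1. Over all 16197 bins a pseudocount of 0.1 gave r of 0.809, 0.827, 0.824, 0.941, 0.932 and 0.953 for these pairs, against 0.829, 0.843, 0.840, 0.954, 0.948 and 0.962 as reported. The cause of these moves was not tested.

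Named genes gave the same call in 383 of 389 values and named bins in 191 of 191, and no named gene or bin reversed. List members called in the report gave the same call on 24-nt reads in 29 of 36 values for TAS loci, 33 of 36 for methylation targets, 30 of 36 for transposable element genes, 24 of 24 for pentatricopeptide repeat genes, 48 of 48 for the methylation machinery and 12 of 12 for photosynthesis genes. On 21-nt reads they did so in 26 of 60 for TAS loci and 55 of 84 for pentatricopeptide repeat genes. Members not called in the report gained a call on 24-nt reads in 3 of 48 values for TAS loci, 7 of 60 for methylation targets, 4 of 36 for transposable element genes, 1 of 24 for the methylation machinery and 0 of 12 each for pentatricopeptide repeat and photosynthesis genes, and on 21-nt reads in 6 of 24 for TAS loci and 5 of 48 for pentatricopeptide repeat genes. For the miRNA lists these were 2 of 36 (phase change), 2 of 60 (trans-acting siRNAs), 2 of 60 (nutrient) and 2 of 36 (small RNA pathway). Depth limits the shallow libraries most: 1 read corresponds to 0.785 RPM in nrpe1 replicate 1 and to 0.061 RPM in dms3.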

Other observations

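Tests described in this part were all chosen after the results were seen. Reads of 21 and 22 nt were tested in the same bins, on the library size without a scaling factor. Of 316 bins that fell at 24 nt and had enough 21-nt reads to be tested, 91 also fell at 21 nt and 6 rose, and of 94 bins that rose at 24 nt, 86 rose at 21 nt and 0 fell. At 22 nt, 158 of 419 bins that fell at 24 nt fell and 3 rose, and 123 of 139 bins that rose at 24 nt rose. Over all tested bins, the median log2 fold change was 0.77 at 21 nt (93 lower and 759 higher of 2036 by edgeR's quasi-likelihood test) and 0.44 at 22 nt (160 and 522 of 2552). With TMM factors the balance turned, to 177 lower and 78 higher at 21 nt and 244 and 136 at 22 nt, and of the bins that rose at 24 nt 52 and 89 rose, while of those that fell at 24 nt 167 and 228 fell and 0 rose. Scaled on listed miRNAs the counts were 121 and 82, and 262 and 86, and of the bins that rose at 24 nt 55 and 75 rose, while of those that fell at 24 nt 118 and 240 fell and 0 rose. Among 24-nt reads, 58.0% to 61.1% began with A in Col-0 and 59.6% to 63.1% in nrpe1, against 46.1% in the T+S wild type, 39.8% to 43.2% in dms4, drd1, dms3 and rdm1, 27.5% in nrpd1 and 26.6% in rdr2.

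The 15 listed genes that fell in nrpe1 at 24 nt were followed in the mutants of the T+S line, which have 1 library each, as log2 ratios to the T+S wild type. In dms4, drd1, dms3 and rdm1 in turn they were -2.13, -2.70, -3.50 and -3.75 for SUVH9, -1.59, -1.79, -1.73 and -1.64 for NRPD2A, -2.98, -1.76, -2.02 and -1.79 for DCL3, and -3.14, -3.16, -3.37 and -3.92 for FWA. They were -3.72, -3.92, -3.99 and -4.31 for AT1G58140, -0.77, -1.20, -1.10 and -0.90 for AT1G21945, -4.85, -4.85, -4.40 and -4.47 for RPF3, and -5.73, -4.14, -4.39 and -4.62 for AT1G63630. TASIR-ARF had -5.45, -4.20, -3.57 and -3.51 and TAS3 had -1.94, -2.53, -2.56 and -2.09. Other listed genes fell less or differed between the mutants: DMS11 had -5.83, -5.45, -0.88 and -0.54, ALN -1.31, -0.82, -0.55 and -0.41, PUM9 0.29, -1.66, -1.10 and -0.62, LHCA3 -0.88, -0.57, -0.48 and 0.04, and TAS1A -1.03, 0.11, -0.20 and 0.11. The T+S wild type had 1.76 RPM at NRPD2A, 2.74 at LHCA3, 2.93 at AT1G21945 and 7.24 at SUVH9. The Col-0 means there were 18.4, 30.3, 16.3 and 42.5 RPM. At FWA, RPF3, AT1G63630 and DMS11 the T+S wild type lay above the Col-0 mean, and at the other listed genes below it. With a pseudocount of 0.5 RPM a low control limits how far a ratio can fall, so the sizes cannot be compared between genes.

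The bins that rose in nrpe1 were weighed further. The choice of scaling alone was argued against for 247 of these 1425 bins, which were higher with the library size, under each of 4 other scalings and with DESeq2, which also changes the test, and stays open for the other 1178. A property of the 6 Col-0 and nrpe1 libraries alone was weighed as well. In the 4 mutants of the T+S line, which are other libraries, the median log2 ratio of these bins was 0.78 to 0.96. The highest matched random set had 0.32, but the sets were drawn from all tested bins. They thus held bins that fell in nrpe1, which lowers them. Bins not called in nrpe1, without matching on abundance, had medians of 0.26 to 0.33. The bins that rose lay above both, which argues against a property of those 6 libraries alone. A gain of 24-nt siRNAs in mutants of RNA polymerase V and its partners was tested on the 247 bins in these 4 mutants, against either wild type. With the library size their medians were 0.66 to 1.69, and scaled on listed miRNAs they were 1.22 and 1.24 in dms4 but -0.39 to -0.05 in drd1, dms3 and rdm1, each above every one of 1000 matched random sets. These sets too were drawn from all tested bins, those that fell in nrpe1 included. The lowest value, -0.39, leaves a gain in drd1, dms3 and rdm1 open. Relative to other bins the 247 bins were higher, but whether their level rose depends on the scaling. Listed miRNAs made up 25.9%, 20.4% and 23.7% of the library size in drd1, dms3 and rdm1. They made up 5.1% in the T+S wild type and 5.5% in dms4. In drd1, dms3 and rdm1 most of these reads were miR172a (196164, 163505 and 177983 RPM), so that scaling rests largely on a single sequence there.

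The grouping of samples was examined through the 10 splits of the 5 samples into 3 and 2. The real split gave 6660 changed bins and 3806 changed genes and the highest other split 0 of each, so 1 of 10 splits was as large in both cases, and 10 splits are too few for a share under 0.05.

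Ratios of closely related miRNAs differed between sets of libraries. The ratio of miR159b to miR159a was 1.31 to 2.24 in the Col-0 and nrpe1 libraries and 0.079 to 0.105 in the other 7, and that of miR396b to miR396a was 3.5 to 4.09 and 0.03 to 0.7. Ligation of the barcoded 5′ adapter was argued against, since the members of each pair share their first 20 bases and the sets differed by at least 12.5 times in the first pair and 5.0 times in the other. The mutations were argued against as well, because the lowest Col-0 ratio was 16.4 times and 5.35 times that of the T+S wild type. Another step of library preparation or the material could not be separated from the set, as 0 of 2 sets held both kinds of ratio.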
